A study of Harpegnathos saltator with 14 samples.

How the data were processed

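Poly(A) RNA from whole bodies of the ant Harpegnathos saltator was sequenced in 14 libraries, 2 for each of 7 groups: embryos, larvae of instar 1, larvae of instar 4, early pupae, late pupae, adult workers and males. Per the labels' protocols, RNA was extracted with TRIzol, treated with DNase, fragmented, reverse transcribed with random hexamers, and made into strand-specific libraries by dUTP incorporation. The labels give no source animals or colonies for the replicates, so p-values measure only the spread between these libraries, which may be partly technical. Groups were taken from the sample labels.

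The deposited values are RPKM, reads scaled to gene length and library size, computed by the authors for 20755 gene models. STAR 2.5.0b and DESeq2 are named with no role, per the submitters' processing notes. The read counter, the genome build and the gene lengths used for the RPKM are not given in the sources used here. The gene set carries 20317 identifiers that start with HSALG and 438 that start with XLOC. None of them was found in the reference gene name table of assembly Hsal_v8.6, with 0 identifiers matched to its 14329 genes. Genes are therefore given by identifier, and the 28 gene lists and the tissue marker lists fixed before the data were examined had 0 matched members and gave no test.

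RPKM values keep the steps of whole reads. For each gene a single whole-number length was searched that turned its values in the 14 libraries into whole reads, within a relative tolerance of 1e-05. This succeeded for 18541 of the 18543 genes above 0, or 99.99% of them. The library denominators resolved this way ran from 11378690 to 40062880 reads. Reads in genes summed to between 4233362 and 14111082 per library, or 31.4% to 54.9% of the denominator. The resolved lengths were multiples of 3 in 97.8% of tested HSALG genes and in 37.3% of tested XLOC genes, so most HSALG lengths were taken as coding lengths without UTRs. The RPKM of 1 read at a typical gene ran from 0.0241 to 0.0849 across libraries. Reads without molecular identifiers are not independent molecules, so floors set at 3 reads cover counting error only. On 3 simulated tables with known reads, all 14 read numbers were exact for 99.9% of 12013, 99.8% of 11979 and 99.9% of 11827 genes past the filter. A first form of this step had doubled the lengths and the reads of the deepest library in such a table. A search for common factors was added, and the reads of the deposited table came out the same before and after it.

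Genes with an RPKM of at least 1 in at least 2 of the 14 libraries were tested, 12421 in number. log2(RPKM + 1) was fitted with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance, all 14 libraries in 1 fit and no block. This fit takes 1 spread per gene for all groups, which the groups do not share. The SD across genes of the log2 difference between replicates ran from 0.312 in workers to 1.29 in early pupae. The p-values of a comparison therefore also reflect the spread of groups outside it. Fold changes are on this log2 scale, which understates the change of low genes. Adjusted p-values are from limma with Benjamini-Hochberg adjustment within each of 6 two-sided comparisons, and a gene was called at an adjusted p below 0.05. A moderated F test asked which genes varied over the 7 groups. A gene peaked in a group when it was called higher there than in each of the other 6 groups. For each comparison up to 2 identifiers that rose and 2 that fell are named, those with the largest log2 difference among called genes with no overlap between the groups, at least 2-fold change and a mean RPKM of at least 10 in the higher group. This rule and the alternatives were fixed before the data were examined, except those said to be chosen later.

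On 5 simulated tables for males against workers, with 12419 genes of which 200 were changed, limma recovered 4.0% of 2-fold, 32.8% of 4-fold, 71.2% of 8-fold and 80.4% of 16-fold changes. False calls made up 5.38% of its calls, and 0 calls had the wrong direction. The simulation gave all libraries of a gene 1 spread. In the data 10 genes lay at least 4-fold apart between the worker libraries and 1224 between the early pupa libraries. These rates therefore need not hold for the deposited table. Correlations, identifier comparisons and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

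Alternatives were a pseudocount of 0.1, no filter, a filter at a mean RPKM of 5, median and quantile scaling between libraries, no variance trend, an added 2-fold minimum, a replicate block, fits of only the 4 libraries compared, and leaving out each library. Added after seeing the data were fits without both early pupa libraries, with library weights, with limma-voom on the resolved reads, and with a crossed replicate block. The crossed block was fitted to only the 4 early and late pupa libraries. No count model was used as the main test, because the deposited values are RPKM. The files give no gene classes, so the planned comparison of expression breadth was made between the HSALG and XLOC forms of identifier, with the tau index, which is higher where expression is narrower.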

Results

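Whole-body transcriptomes of Harpegnathos saltator, a ponerine ant, were compared over development, from the embryo through larvae of instars 1 and 4, early and late pupae and the adult worker, and with males, whose age the labels do not give. Each of the 7 groups had 2 libraries. Reads in genes numbered from 4233362 in male replicate 2 to 14111082 in late pupa replicate 2, and between 8860 and 11133 genes reached an RPKM of 1. The share of gene reads taken by the 10 most abundant genes ran from 6.70% in embryo replicate 2 to 61.6% in instar 4 replicate 2. A single gene, HSALG006290.2, took 29.5% and 30.6% of gene reads in the instar 4 libraries and 27.0% in early pupa replicate 2. XLOC_066657 took 16.7% and 13.1% in the late pupa libraries.

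Replicates of workers were the closest, with a Pearson r of 0.986 across genes, followed by instar 4 larvae at 0.976, instar 1 larvae at 0.944, males at 0.928, late pupae at 0.916 and embryos at 0.885. Early pupae stood apart at 0.689, with 1224 genes at least 4-fold apart between their libraries against 10 in workers and 525 in embryos. Early pupa replicate 1 was closest to late pupa replicate 2 (r = 0.932), and early pupa replicate 2 to instar 4 replicate 1 (r = 0.933). Late pupa replicate 2 was in turn closer to early pupa replicate 1 than to late pupa replicate 1. With worker replicates 1 and 2, late pupa replicate 2 had r of 0.583 and 0.585, against 0.699 and 0.696 for late pupa replicate 1. Genes are not independent replicates, so these correlations describe the libraries and carry no test.

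**Figure D1:**
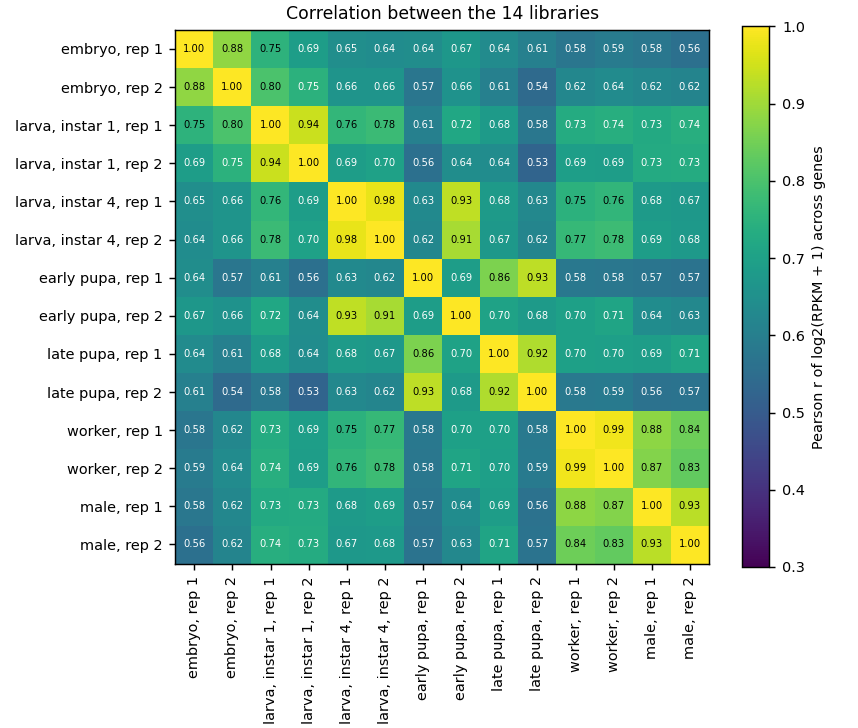
Pearson r of log2(RPKM + 1) across 12421 genes for each pair of the 14 libraries, on a color scale from 0.3 to 1. The early pupa libraries reach 0.689 with each other, and 0.932 and 0.933 with a late pupa and an instar 4 library.

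Expression differed over development for most genes. Of 12421 genes tested, 8679 varied over the 7 groups (69.9%), and 960 of these spanned at least 16-fold between their highest and lowest group means. The highest mean of varying genes lay in embryos for 4236 genes, in instar 1 larvae for 1150 and in males for 1092. The lowest lay in instar 4 larvae for 3359 genes. These tallies used RPKM as deposited and were not repeated under other scalings. In the instar 4 libraries 10 genes took 60.6% and 61.6% of gene reads, which lowers the RPKM of all other genes. Low expression in instar 4 cannot be told apart from this share. Genes higher in 1 group than in each of the other 6 numbered 1107 in embryos, 137 in males, 132 in instar 1 larvae, 82 in workers, 14 in late pupae, 13 in instar 4 larvae and 0 in early pupae, where limma at unadjusted p below 0.05 gave 23. The order depended on the scaling: median scaling gave 226 in embryos and 468 in instar 1 larvae, and quantile scaling 269 and 221. The numbers also depended on the libraries: late pupae had 281 without early pupa replicate 1, above workers at 106. Instar 4 larvae had 126 and early pupae 49 without early pupa replicate 2, and embryos 415 without instar 1 replicate 2.

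Passage from embryo to instar 1 larva switched on genes that were close to silent in the embryo. HSALG004217.2 rose from 0.882 ± 0.208 to 3210 ± 916 RPKM (mean ± SD, n = 2), a log2 difference of 10.71 ± 0.76 (SE; limma, Benjamini-Hochberg adjusted p = 1.43e-05). HSALG005183.2 stood at 1438 ± 816 RPKM in the larvae (n = 2), where the embryo libraries held 1 and 0 reads, with a log2 difference of 10.33 ± 0.68. HSALG015784.1 fell from 1050 ± 276 to 1.73 ± 1.77 RPKM (n = 2), a log2 difference of -8.73 ± 0.42 (limma, adjusted p = 8.83e-07). HSALG028355.1 fell from 993 ± 969 to 0.717 ± 0.510 RPKM (n = 2), and both genes that fell peaked in the embryo. Across all genes, 520 were called higher and 2944 lower in instar 1 larvae, with 77 and 81 of them changed at least 16-fold. The median of all genes lay at -0.55 on the log2 scale, and scaling the libraries to a common median gave 1594 higher and 1165 lower, with quantile scaling at 776 and 996. With only the 4 libraries of these groups limma called 72 genes, 38 higher and 34 lower, so the direction of the majority turned under median scaling and with these libraries alone, and not under quantile scaling. Calls fell to 226 higher and 672 lower without instar 1 replicate 2 and to 276 and 1811 without embryo replicate 1.

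Between the first and the fourth instar the larval transcriptome came to be dominated by few genes. HSALG006290.2 rose from 4.94 ± 0.259 to 55900 ± 1461 RPKM (n = 2), a log2 difference of 13.20 ± 1.27 (limma, adjusted p = 0.000191). HSALG008021.1 rose from 0.420 ± 0.196 to 7387 ± 2940 RPKM (n = 2), a log2 difference of 12.29 ± 1.96 (limma, adjusted p = 0.00109). A pair of genes abundant in instar 1 fell: HSALG008802.2 from 19303 ± 7888 to 13.5 ± 1.95 RPKM and HSALG003196.2 from 12216 ± 5134 to 4.54 ± 0.906 RPKM (n = 2). Their log2 differences were -10.32 ± 1.34 and -11.05 ± 1.34 (limma, adjusted p = 0.000372 and 0.000325), and both peaked in instar 1. In total 649 genes were called higher and 2938 lower in instar 4, with 57 and 56 changed at least 16-fold. The median of all genes lay at -0.36, and the split became 1613 higher and 2313 lower under median scaling and 1626 and 2058 under quantile scaling. Calls fell to 231 higher and 1649 lower without instar 4 replicate 1, to 286 and 1543 without replicate 2, and to 247 and 2482 without instar 1 replicate 2.

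**Figure D2:**
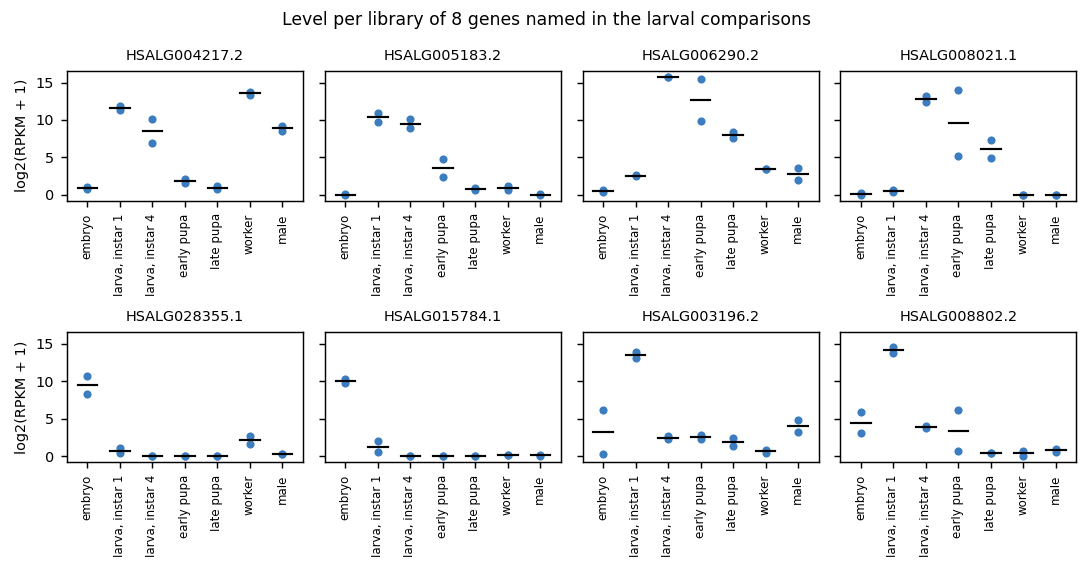
Level per library, as log2(RPKM + 1), of 8 genes named for the embryo to instar 1 and the instar 1 to instar 4 comparisons, in the 7 groups; points are the 2 libraries of a group and bars their mean. HSALG006290.2 reaches 55900 RPKM in instar 4 larvae, and its early pupa libraries lie far apart.

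From instar 4 larva to early pupa 78 genes were called. HSALG025397.1 fell from 1362 ± 426 to 8.16 ± 2.93 RPKM (n = 2), a log2 difference of -7.22 ± 0.56 (limma, adjusted p = 0.000277). HSALG004476.2 fell from 6194 ± 6333 to 35.7 ± 0.689 RPKM (n = 2), a log2 difference of -6.86 ± 0.88. XLOC_057380 rose from 1.58 ± 0.768 to 38.3 ± 24.6 RPKM (n = 2), a log2 difference of 3.80 ± 0.62 (limma, adjusted p = 0.0204). HSALG001120.2 rose from 2.24 ± 1.11 to 68.5 ± 69.2 RPKM (n = 2), with adjusted p = 0.0337 from limma, a call lost in 15 of 25 alternatives, where adjusted p reached 0.494. The calls of XLOC_057380, HSALG004476.2 and HSALG025397.1 were lost in 6, 2 and 1 of 25. Calls numbered 32 higher and 46 lower, with 18 of the lower ones changed at least 16-fold, and the split was 23 and 56 under median scaling and 30 and 95 under quantile scaling. The median of all genes lay at 0.45 on the log2 scale. The direction of the majority turned without early pupa replicate 2, with 2674 higher and 502 lower, without early pupa replicate 1, with 36 and 27, and with log2(RPKM + 0.1), with 48 and 42. Calls numbered 0 higher and 18 lower without instar 4 replicate 2, 9 and 25 without replicate 1, and 46 in all without either worker library. limma called 0 genes when only the 4 libraries of these groups were fitted, where 1098 had an unadjusted p below 0.05.

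Late pupae were set against early pupae whose libraries lay far apart, and the calls depended on the early pupa library used. HSALG005524.1 rose from 8.79 ± 12.0 to 691 ± 252 RPKM (n = 2), a log2 difference of 7.08 ± 0.86 (limma, adjusted p = 0.0108). HSALG006686.1 rose from 0.391 ± 0.445 to 248 ± 295 RPKM (n = 2), a log2 difference of 6.65 ± 0.80, and peaked in late pupae. The call of each was lost in 4 of 26 alternatives, where adjusted p from limma reached 1, and that of HSALG005524.1 was lost without late pupa replicate 1 (limma, adjusted p = 0.0744). The 1 gene called lower was HSALG002662.1, at 74.96 ± 42.6 RPKM in early and 8.68 ± 1.90 RPKM in late pupae (n = 2), with adjusted p = 0.0499 from limma. That call was lost in 24 of 26 alternatives, over which adjusted p ran from 0.00154 to 1. Calls numbered 21 higher, 12 of them at least 16-fold, and 1 lower, out of 823 genes at unadjusted p below 0.05. Without early pupa replicate 2 the majority turned, with 19 higher and 56 lower, and without replicate 1 there were 728 higher and 431 lower. The count fell to between 5 and 14 without any 1 of the other libraries except late pupa replicate 2. limma called 12 genes under median scaling and 0 with only these 4 libraries, where 292 genes had an unadjusted p below 0.05.

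**Figure D3:**
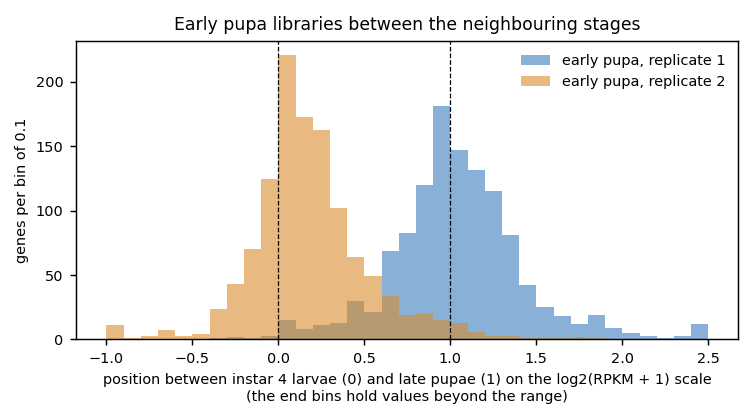
Position of each early pupa library between the means of instar 4 larvae (0) and late pupae (1) for 1182 genes at least 4-fold apart between those groups, in genes per bin of 0.1. Replicate 1 has its median at 1.02 and replicate 2 at 0.14.

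From late pupa to adult worker 1306 genes were called. limma gave 3289 with only the 4 libraries of these groups (1922 higher and 1367 lower) and 4217 with library weights. XLOC_066657 stood at 48291 ± 9259 RPKM in late pupae (n = 2), where the worker libraries held 3 and 0 reads, with a log2 difference of -15.48 ± 2.37 (limma, adjusted p = 0.00181). HSALG003463.2 fell from 39876 ± 42677 to 0.795 ± 0.289 RPKM (n = 2), a log2 difference of -13.84 ± 2.36. HSALG004217.2, which rose in instar 1 larvae, rose again from 0.963 ± 0.419 to 12178 ± 2429 RPKM (n = 2), a log2 difference of 12.60 ± 0.76 (limma, adjusted p = 1.51e-06). HSALG012385.1 rose from 1.48 ± 0.816 to 8962 ± 1185 RPKM (n = 2) and peaked in workers. In all 917 genes were called higher and 389 lower in workers, with 159 and 117 changed at least 16-fold, and the split was 1000 and 741 under median scaling and 952 and 781 under quantile scaling. The count rose to 2249 without both early pupa libraries and to 2245 and 2246 without replicate 1 or 2 of them. The count dropped to 433 and 499 without worker replicate 2 or 1, and to 479 and 868 without late pupa replicate 2 or 1.

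Males and adult workers differed in 371 genes. HSALG011610.2 stood at 839 ± 169 RPKM in males (n = 2) and held 0 reads in both worker libraries, which makes it at least 1766-fold higher over a floor of 3 reads in 1 library (limma, adjusted p = 6.74e-09). HSALG008444.1 stood at 3006 ± 1738 RPKM in males (n = 2) against 2 and 0 reads in workers, a log2 difference of 11.32 ± 0.48, and both genes peaked in males. HSALG001655.2 was lower in males, at 4.18 ± 0.920 against 2745 ± 63.3 RPKM (n = 2), a log2 difference of -9.06 ± 1.00 (limma, adjusted p = 0.000356), and peaked in workers. HSALG013889.2 stood at 1.40 ± 1.01 in males against 1836 ± 13.3 RPKM in workers (n = 2), a log2 difference of -9.65 ± 1.42. In all 210 genes were called higher and 161 lower in males, with 30 and 45 changed at least 16-fold. The majority turned to 202 higher and 204 lower under quantile scaling, to 93 and 133 with only the 4 libraries of these groups, and to 59 and 74 without worker replicate 1. The count rose to 679 without both early pupa libraries, and to 675 and 680 without replicate 1 or 2 of them, and fell to 115 without worker replicate 2 and to 193 without male replicate 2.

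**Figure D4:**
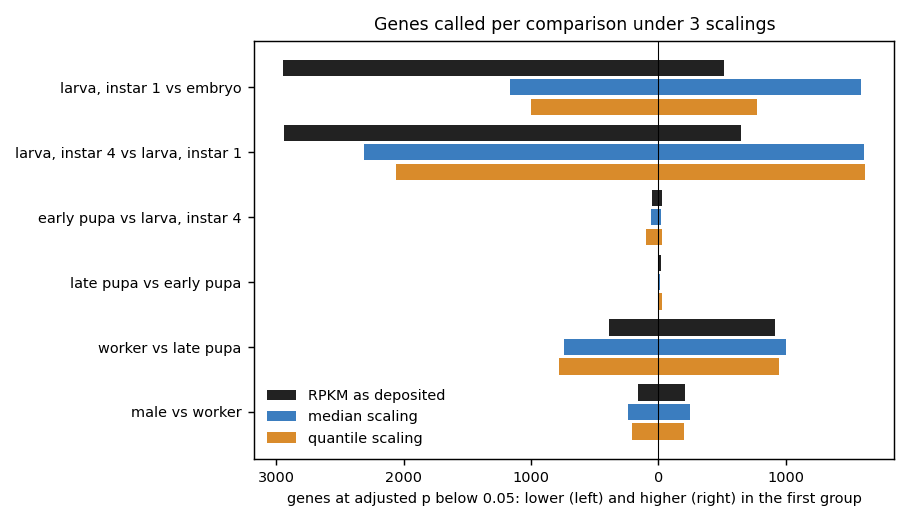
Genes at adjusted p below 0.05 (limma) in the 6 comparisons, lower to the left and higher to the right of 0, with RPKM as deposited and after median or quantile scaling. For instar 1 larvae against embryos, 2944 lower genes become 1165 and 996.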

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

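The fits without both early pupa libraries, with library weights, with limma-voom and with a crossed block were chosen after seeing the data. Over 27 settings, 236 of 354 alternative counts stayed within 1.5 times and 118 moved. Of 594 alternative values of named genes, 538 kept direction and call, 56 lost the call, all in the pupal comparisons, and 0 reversed. Causes were not tested except where fewer genes or libraries enter.

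Counts that moved are given as total calls. With log2(RPKM + 0.1), late against early pupae gave 12, and genes peaking in instar 4, late pupae and workers 2, 8 and 47. With no filter, 2 genes peaked in early pupae. At a mean RPKM of 5, which tests fewer genes, 5658 genes varied, instar 1 against embryo gave 2258, late against early pupae 10, and peaks in embryo, instar 4, late pupae and workers were 702, 2, 8 and 47. Median scaling gave 12 for late against early pupae and 226 and 468 peaks in embryo and instar 1. Quantile scaling gave 1772 for instar 1 against embryo, 125 for early pupae against instar 4, and 269, 221 and 36 peaks in embryo, instar 1 and instar 4. Without the trend, late against early pupae gave 14 and late pupae 9 peaks. With only the 4 libraries compared, instar 1 against embryo gave 72, both pupal comparisons 0, worker against late pupa 3289 and male against worker 226. Without both early pupa libraries, worker against late pupa gave 2249, male against worker 679, and embryo, instar 4 and late pupae 1669, 144 and 382 peaks. Library weights gave 16, 6, 4217 and 969 calls for early pupae against instar 4, late against early pupae, worker against late pupa and male against worker, and 249, 71, 7 and 5 peaks in embryo, instar 1, instar 4 and late pupae. limma-voom gave 44 and 8 calls in the pupal comparisons and 2, 5 and 52 peaks in instar 4, late pupae and workers.

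The labels do not say what the replicate numbers stand for. Deviations of same-numbered libraries correlated between -0.26 and 0.15 over 21 pairs of groups, so the numbers were not taken as pairs. The replicate block gave 3325, 3413, 66, 15, 1209 and 297 calls in the 6 comparisons in order of development and 6 peaks in instar 4. A crossed block for late against early pupae was fitted to only the 4 libraries of these groups. It gave 0 calls in limma, with 375 genes at unadjusted p below 0.05. The same 4 libraries without a block also gave 0 calls.

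A group left with 1 library was assumed to vary like the others. Leaving out each library gave 6818 to 10293 varying genes, 898 to 4447 calls for instar 1 against embryo, 1829 to 4410 for instar 4 against instar 1, 18 (without instar 4 replicate 2) to 3176 (without early pupa replicate 2) for early pupae against instar 4, 5 to 1159 (without early pupa replicate 1) for late against early pupae, 433 to 2246 (without early pupa replicate 2) for worker against late pupa, and 115 to 680 (without early pupa replicate 2) for male against worker. Peaks ran from 415 (without instar 1 replicate 2) to 1400 in embryo, 43 (without instar 1 replicate 2) to 185 in instar 1, 2 (without instar 4 replicate 1) to 126 (without early pupa replicate 2) in instar 4, 0 to 49 (without early pupa replicate 2) in early pupae, 4 to 281 (without early pupa replicate 1) in late pupae, 36 (without worker replicate 2) to 106 in workers and 52 (without worker replicate 1) to 225 (without male replicate 1) in males.

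The median tau index, higher where expression is narrower, was 0.0374 higher in XLOC than in HSALG genes (permutation p = 0.00113 over genes, which are not independent). The difference, XLOC minus HSALG, turned to -0.00754 at a mean RPKM of 5 (permutation p = 0.548) and came to 0.000397 after matching on level (permutation p = 0.959). The planned gene list tests were not run, since 0 identifiers matched a name.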

Other observations

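Genes that rose at hatching often rose again in the adult worker, in overlaps chosen for testing after the data were seen. Of 520 genes that rose from embryo to instar 1 larva and 917 that rose from late pupa to worker, 201 were shared, where independent lists would share 38.4 (Fisher's exact test, Benjamini-Hochberg adjusted p = 2.05e-95 over 40 tests). By contrast, 22 of the 520 fell from late pupa to worker, with 16.3 for independent lists. The shared genes numbered 338 against 128 under median scaling and 210 against 59.5 under quantile scaling. Of 46 genes that fell from instar 4 larva to early pupa, 24 rose from late pupa to worker against 3.40 for independent lists, and 11 were lower in males than in workers against 0.596. Of the 32 that rose into the early pupa, 12 fell from late pupa to worker against 1.00. These comparisons share no library, but the joint limma fit gives each gene 1 estimate of spread for all comparisons, which can raise the overlap in either direction. Genes are also not independent, so the Fisher p-value does not measure the spread between libraries.

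Of the tests below, those on the early pupae, on the choice of XLOC loci and on distant identifiers were chosen after the result was seen. The test of age replaced an earlier one that was void, since it chose and measured genes against the same instar 4 libraries, and the hypothesis of age came from the libraries it was tested on. A first bound for a wrong label, 3 times the 35 genes between the instar 4 libraries, was passed by the 154 genes given below. It was dropped because it rested on 1 pair of libraries. With the numbers known, it was replaced by the largest number between replicates of the other 6 groups, 525 in embryos, which left a wrong label open.

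The early pupa libraries resembled different neighbouring stages. The best of 8 swaps left a within-group r of 0.704, so no swap made the replicates of both groups agree. Exchanging early and late pupa replicate 1 raised r from 0.689 to 0.704 in early pupae and from 0.916 to 0.932 in late pupae. A swap is therefore left open, though it would not remove the disagreement. Replicate 2 lay at least 4-fold from both instar 4 libraries, in 1 direction, in 154 genes. By the same rule the instar 4 libraries gave 4 and 27, each set against the other and early pupa replicate 2. Taken in pairs, replicate 2 lay at least 4-fold from the instar 4 libraries in 180 and 271 genes. These numbers exceeded the 35 between the instar 4 libraries, but lay inside the 10 to 525 between the libraries of each of the 6 other groups. By that range, a wrong label on replicate 2 alone cannot be told apart from an early pupa. A late pupa wrongly labelled as replicate 1 was not tested beyond the swaps. Replicate 1 was placed over 1182 genes at least 4-fold apart between instar 4 larvae (0) and late pupae (1). Its median position was 1.02, with 81.6% of genes above 0.75. Its r of 0.932 with late pupa replicate 2 exceeded the 0.916 between the late pupa libraries. A mixture of instar 4 and pupal RNA was tested in 2 ways. A first test counted genes at least 4-fold above the other instar 4 and pupal libraries. It found 28 for replicate 2 against 7 and 18 for the instar 4 libraries and missed its bound of 3 times. The rule was stricter for replicate 2, which had to exceed both instar 4 libraries. Each of those had to exceed only the other, with replicate 2 left out, so this test decides nothing. A second test, devised after the first had not decided, covered only RNA like that of replicate 1. A 4-fold fall needs 75% of pupal RNA, and 60 genes lay at least 4-fold below both instar 4 libraries. Of these, 39 had at least 20 RPKM in both. Yet 51 genes abundant in replicate 1 and low in instar 4 reached a median of 0.398% of their level there (quartiles 0.246% and 0.524%). This argues against a mixture with RNA like that of replicate 1. A mixture with other pupal RNA would need 75% of it too. Were that RNA like the late pupa libraries, the 768 genes higher there than in instar 4 larvae would lie close to their level. In replicate 2, 6.35% of the 1182 genes placed between those groups lay above 0.75. This argues against RNA like the late pupa libraries, and a mixture with pupal RNA of another kind was not tested. When genes were chosen at least 4-fold from 1 instar 4 library and measured against the other, 76.7% of 180 and 62.7% of 271 lay at least 2-fold the same way in replicate 1, against at most 52.2% and 42.1% in any library of embryos, instar 1 larvae, workers and males. Among the lower genes replicate 1 reached 88.6% and 75.5%, little above embryo replicate 1 (82.3% and 70.6%). The other libraries compared ran down to 48.1% and 33.3% in worker replicate 2. Late pupae were left out of this comparison. It therefore cannot show whether the shift is particular to replicate 1 or shared with late pupae. In replicate 1, 6.32% of all genes were 2-fold below the instar 4 mean. Of the higher genes 67.3% and 55.0% lay that way in replicate 1, where 34.6% of all genes were 2-fold above the instar 4 mean. A difference in age within the stage is left as a hypothesis. A wrong label on replicate 1, by a swap or otherwise, could meet this test too. So could a mixture with pupal RNA unlike both replicate 1 and the late pupa libraries.

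Genes with XLOC identifiers were highest in males in 101 of 397 cases, or 25.4%, against 11.3% of HSALG genes (Fisher's exact test, adjusted p = 1.2e-13 over 7 groups). They were also more often highest in late pupae (16.4% against 11.3%, adjusted p = 0.00674) and less often in embryos (34.5% against 46.9%, adjusted p = 3.75e-06) and workers (5.04% against 8.16%, adjusted p = 0.042). Genes are not independent, so these Fisher p-values do not measure the spread between libraries. HSALG genes matched on level were highest in males in 10.01% of cases. Over 10000 random draws of matched genes, with the XLOC share held fixed, p was 0.0002, the smallest the draws can give. The excess was 17.5 percentage points with male replicate 1 alone and 8.29 with male replicate 2 alone. Matching on level therefore did not remove the excess in males, and an excess remained with either male library alone, smaller with replicate 2. The excesses with 1 male library were neither matched on level nor tested. Shares of genes highest in males were not repeated under other scalings. Selection of the 101 loci from male RNA cannot be told apart from male biology, since the sources used here do not say how these loci were chosen.

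Consecutive identifiers correlated above 0.9 more often than distant ones. Of 7785 pairs of consecutive HSALG identifiers, 7.48% correlated above 0.9 over the 14 libraries, against 1.12% of pairs 50 places apart, which argues against an effect shared by all genes. Whether consecutive identifiers are pieces of 1 transcription unit cannot be told apart from co-regulation, and no table gives their places in the genome: among pairs correlated above 0.9, the levels of 582 consecutive ones differed less than those of 134 pairs 50 places apart, by -0.42 on the log2 scale (permutation p = 2e-05, the smallest the permutations can give), short of the 0.5 set beforehand. No biological explanation was tested for this pattern.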
